A study of Mus musculus with 6 samples.

How the data were processed

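RNA of lineage-negative, c-Kit-positive mouse bone marrow cells, 3 control and 3 Dars2 knockout samples by their labels, was poly(A)-selected, copied with random hexamers and sequenced with single reads of 150 bases, per the labels' protocols. The submitters' processing notes name STAR 2.7.3a, featureCounts 1.6.2 and the builds GRCm38 and mm10, without giving their roles. The deposited values are log2 RPKM (reads per kilobase of exon, scaled to the library size), per the file headers. The table holds 14367 genes, of which 14214 carry a gene identifier and version of GENCODE M21, the annotation used here for symbols, lengths and coordinates on GRCm38. Another 137 matched M21 without the version, and 16 had no symbol.

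What the values hold was tested on the table itself. For the 14214 of 14367 genes with an M21 exon length, all values (100%), multiplied by that length, fell on whole reads within a tolerance of 0.1 read, so that the deposited log2 values came from read counts with an offset of 2 reads at the mean library size. That offset is 2 over all 6 columns and 1.96 over the 5 distinct ones. No gene in the table lies below 1.025 CPM (reads scaled to the library size) in its third-highest column, so genes had been filtered with the identical columns counted separately. That filter is not given in the sources used here. The recovered reads per library were 24252016, 24887902 and 9755603 for control replicates 1, 2 and 3, and 24015387 and 24357479 for the knockout libraries. Control replicate 3 therefore gives the least precise low values.

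The columns of knockout replicates 1 and 2 were identical in 14367 of 14367 rows, and the other 14 pairs of columns in at most 7. They were used as 1 library. Within groups the mean chi-square of 2 libraries per gene was 1.73 to 2.57 for pairs of controls and 2.00 for the knockout pair, where 1 is pure counting noise, and 55.0 to 92.5 between groups.

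The test was chosen before the data were examined, for counts with a second form for normalized values. Since the table holds log2 RPKM, the second form was used: values were turned back to RPKM, log2(RPKM + 1) was taken, and genes with at least 1 RPKM in at least 3 of the 6 columns were kept, 12732 in all. A gene above 1 RPKM only in the knockout thus needed 2 distinct libraries, and one above it only in the controls needed 3. Counts and tests of lists with members that are low in the controls therefore lean toward a rise. The pseudocount makes differences of low genes smaller than their ratio. The only departure was that the identical columns entered the fit once. limma 3.58.1 in R 4.3.3 was fitted with genotype as the only term (lmFit, eBayes with trend and robust moderation; 3 residual and about 3.23 prior degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. RPKM are printed as means ± SD, and log2 differences are knockout minus control. In all, 36 gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Genes were named by a rule fixed before the data were examined: Dars2, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap and whose mean is at least 1 RPKM, without predicted genes and immunoglobulin, T cell receptor or histone segments, and up to 4 members of each list with the smallest adjusted p, or the 2 most abundant where none passed. Exceptions are said to have been named after their values were seen.

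The same code was tested on simulated libraries with the depths of the real ones, the means of the controls and a spread pooled over 1 pair of libraries per group. For control replicates 1 and 2 the mean chi-square per gene was 1.96 in the simulation and 2.57 in the real libraries, at unlike minimum reads. The simulated spread may therefore be too small. Of genes changed by 0.25, 0.5, 1 and 2 on the log2 scale, 26.1%, 64%, 96% and 100% were recovered among 12159 genes, and 5.96% of the calls were false. Only 196 of these genes were changed, all drawn from well-expressed ones, whereas 53.6% of the genes tested were called in the real data. The recovered and false shares therefore need not hold there. Of 30 simulated lists the shifted one was called and none of the others. Simulated genes varied independently of each other, so this does not check camera's preset correlation. Alternatives fixed beforehand were a replicate block, each library left out, quantile normalization, scaling without hemoglobin and mitochondrial genes, no filter, a mean of at least 5 RPKM, limma without trend or robust moderation, a pseudocount of 0.1, a log2 difference of at least 1, and the other list tests. Added after seeing the data were the deposited log2 values without a further pseudocount, a filter on 3 distinct libraries, limma-voom on the recovered reads, the identical columns as separate libraries, and either number for them in the block. Of 157 named genes, 52 have exons that overlap another annotated gene; the protocol names no step that keeps strand, so reads of such pairs cannot be told apart. Splicing was not analysed here.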

Results

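Poly(A)-selected RNA of lineage-negative, c-Kit-positive cells of mouse bone marrow was sequenced in 3 control samples and 3 samples of cells in which Dars2 was knocked out. These cells, sorted for the absence of markers of mature blood cells and for the stem cell factor receptor c-Kit, hold the hematopoietic stem and progenitor cells. Dars2 encodes the mitochondrial aspartyl-tRNA synthetase, which charges the transfer RNA for aspartate in mitochondria. The sample titles give the controls as Dars2f/f and the knockout samples as Dars2-KO. The columns of knockout replicates 1 and 2 held identical values in all 14367 genes, so they differed by less than sampling noise and were counted as 1 sample. The comparison therefore rested on 3 control and 2 distinct knockout libraries. The reads recovered per control library were 24252016, 24887902 and 9755603, and per knockout library 24015387 and 24357479. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

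Dars2 (ENSMUSG00000026709.10, GRCm38 chromosome 1, 161040601 to 161070658, minus strand, protein-coding) was read first as the check of the genotype labels. It stood at 5.06, 6.0 and 5.76 RPKM in control replicates 1, 2 and 3, and at 2.39 and 2.82 RPKM in the knockout libraries. The group means were 5.60 ± 0.49 RPKM (SD, n = 3) and 2.61 ± 0.30 RPKM (SD, n = 2), a log2 difference of -0.87 with a standard error of 0.09 on the log2(RPKM + 1) scale (limma, adjusted p = 0.000335). From 301 to 359 reads remained on the gene in the knockout libraries, and the gene-level values do not show which exons they came from. An exon of Dars2 overlaps an annotated gene on the opposite strand, and the library protocol names no step that marks strand.

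The question of the comparison was which genes differ in expression between the knockout and control libraries of sorted cells. Each library is a bulk of cells. For all lists below, changed shares of cell types therefore cannot be told apart from changed expression within cells. Of 12732 genes tested, 3355 were higher and 3469 lower in the knockout libraries at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), 6824 in all. The balance of directions depended on the processing: 3607 were higher and 3208 lower with hemoglobin and mitochondrial genes left out of the scaling, 3048 and 3903 after quantile normalization, and 3849 and 3622 with no low-expression filter. With a mean RPKM of at least 5, 1932 were higher and 2825 lower among 8232 genes tested. By at least 1 on the log2(RPKM + 1) scale 486 genes were higher and 204 lower, and 228 and 144 with a mean RPKM of at least 5. Tests added after the data were seen gave 849 and 313 with the deposited log2 RPKM and no added pseudocount. They gave 861 and 318 with limma-voom on recovered reads, and 376 and 204 with a filter on 3 distinct libraries. The first principal component held 90.3% of the variance and separated both knockout libraries from the 3 controls. With 3 against 2 libraries, 20% of unchanged genes have groups that do not overlap by chance, and an exact permutation test of 1 gene could not fall below p = 0.1. Of the 36 gene lists fixed before the data were examined, 27 differed from the other genes with camera's preset correlation, and 10 of these held with an estimated correlation. Unless another count is given, the counts of members adjusted over the list alone were those over all genes tested.

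The targets of ATF4, CHOP and the integrated stress response, the program that cells use on amino acid shortage and mitochondrial stress, rose in the knockout libraries. Of 34 measured members 32 rose, 1 fell and 1 did not pass the threshold, with a median log2 difference of 1.02 (camera, adjusted p = 3.1e-16, and 0.038 with an estimated correlation). Gdf15, a stress cytokine (GRCm38 chromosome 8, 70629393 to 70632456), rose from 2.39 ± 0.24 RPKM (SD, n = 3) to 21.2 ± 0.033 RPKM (SD, n = 2). Trib3, a pseudokinase induced by ATF4, rose from 16.8 ± 1.4 to 88.0 ± 0.25 RPKM, and the transcription factor Atf5 from 64.0 ± 1.8 to 224 ± 2.8 RPKM. Mthfd2, an enzyme of mitochondrial one-carbon metabolism, rose from 24.1 ± 0.46 to 66.5 ± 0.88 RPKM. The member that fell was Atf3, with a log2 difference of -0.34, and Ppp1r15a had a difference of -0.02; both were named after their values were seen.

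**Figure D1:**
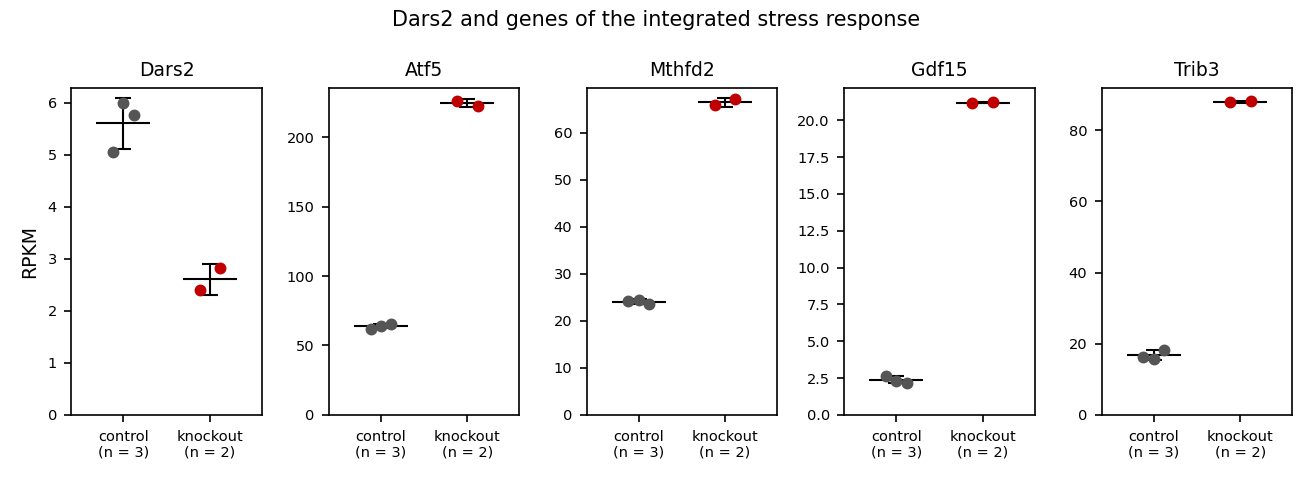
RPKM (y axis, linear, from 0) of Dars2 and 4 genes of the integrated stress response in each library, with control libraries in grey (n = 3) and distinct knockout libraries in red (n = 2); horizontal marks are group means and bars are SD. Both knockout values of Dars2 lie below the lowest control value, 5.06 RPKM, and both knockout values of the other 4 genes lie above all control values.

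Among the cytosolic aminoacyl-tRNA synthetases 12 of 20 rose, 5 fell and 3 did not pass, with a median log2 difference of 0.38 (camera, adjusted p = 0.015). With an estimated correlation that list's adjusted p = 0.203. Sars, the seryl-tRNA synthetase, rose from 29.2 ± 0.93 to 54.6 ± 0.77 RPKM, Aars, the alanyl-tRNA synthetase, from 20.2 ± 0.25 to 36.6 ± 0.091 RPKM, and Gars and Nars had log2 differences of 0.52 and 0.46. The members that fell were Hars, Qars, Kars, Farsa and Vars, named after their values were seen. Genes of cytosolic ribosomal proteins rose in 55 of 64 cases and fell in none, or 59 adjusted over the list alone, with a median log2 difference of 0.28 (camera, adjusted p = 1.1e-13). With an estimated correlation the adjusted p = 0.195. In the libraries in which these lists and the stress response targets moved, the lineage lists had medians of -1.54 for erythroid, -0.63 for promyelocyte and 2.25 for late neutrophil genes. Rps24 rose from 269 ± 6.0 to 378 ± 5.0 RPKM and Rps14 from 593 ± 15 to 824 ± 4.2 RPKM.

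Targets of p53, the transcription factor of the DNA damage response, rose in 18 of 25 measured cases, or 19 adjusted over the list alone, and none fell. Their median log2 difference was 0.56 (camera, adjusted p = 5.4e-08, and 0.038 with an estimated correlation). Eda2r, Trp53cor1, Tnfrsf10b and Fas, named after their values were seen, had control means from 0.427 to 0.775 RPKM. They passed the filter only through the knockout columns, so the count and p-value of the p53 list lean toward a rise. Cdkn1a, an inhibitor of cyclin-dependent kinases, rose from 13.5 ± 0.35 to 46.5 ± 0.51 RPKM, and Phlda3, a repressor of AKT, from 4.64 ± 0.26 to 18.8 ± 0.95 RPKM. Psrc1 and Trp53inp1 had log2 differences of 1.40 and 1.48. Genes of S phase and replication fell in 28 of 32 cases, or 29 adjusted over the list alone, and none rose (median log2 difference -0.30, camera, adjusted p = 8.0e-10, and 0.038 with an estimated correlation). Ccne1, cyclin E1, fell from 20.7 ± 1.3 to 6.32 ± 0.33 RPKM, and Rrm2, a subunit of ribonucleotide reductase, from 84.9 ± 2.3 to 51.8 ± 0.091 RPKM. Mcm5 and Mcm7 of the replicative helicase both had log2 differences of -0.53. Of 32 genes of G2 and mitosis 26 fell and none rose (median log2 difference -0.31, camera, adjusted p = 1.0e-06, and 0.038 with an estimated correlation), among them the proliferation marker Mki67, from 51.9 ± 0.35 to 38.6 ± 0.86 RPKM, and the centromere histone Cenpa, from 23.3 ± 0.025 to 15.5 ± 0.54 RPKM. The p53 and cell cycle lists moved in libraries in which the erythroid median was -1.54, the promyelocyte median -0.63 and the late neutrophil median 2.25. Whether they moved within cells or through changed shares of cell types cannot be told apart here. Of the BCL2 family and caspase genes 8 of 24 rose and 7 fell, with a median log2 difference of 0.02 and a test that pointed lower (camera, adjusted p = 0.970). Casp3, an executioner caspase, fell from 65.8 ± 0.97 to 30.1 ± 0.33 RPKM, and Bcl2, an inhibitor of apoptosis, rose from 6.19 ± 0.23 to 8.90 ± 0.043 RPKM.

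Of 35 nuclear complex I genes 19 fell in the knockout libraries and none rose (median log2 difference -0.17, camera, adjusted p = 0.0024, and adjusted p = 0.224 with an estimated correlation). After quantile normalization this list did not pass (adjusted p = 0.074). Of 39 genes of complexes II, III, IV and ATP synthase 30 fell and 2 rose (median -0.23, camera, adjusted p = 1.9e-06, and adjusted p = 0.159 with an estimated correlation). Ndufb10 of complex I fell from 68.2 ± 0.69 to 49.2 ± 1.2 RPKM, and Atp5g3 of ATP synthase from 113 ± 2.3 to 82.6 ± 1.8 RPKM. The complex II to ATP synthase members that rose were Cox7a2l and Uqcrq, named after their values were seen. Mitochondrial ribosomal protein genes fell in 34 of 75 cases and rose in 2, Mrps6 and Mrpl24 (median -0.12, camera, adjusted p = 0.0015, and adjusted p = 0.136 with an estimated correlation). Mrpl24 was named after its values were seen. The erythroid median was -1.54 and the late neutrophil median 2.25 in these libraries. Mrpl18 fell from 66.0 ± 3.2 to 49.2 ± 0.43 RPKM, and Mrps6 rose from 6.81 ± 0.48 to 13.6 ± 0.62 RPKM, but its exons overlap Slc5a3 on the same strand.

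**Figure D2:**
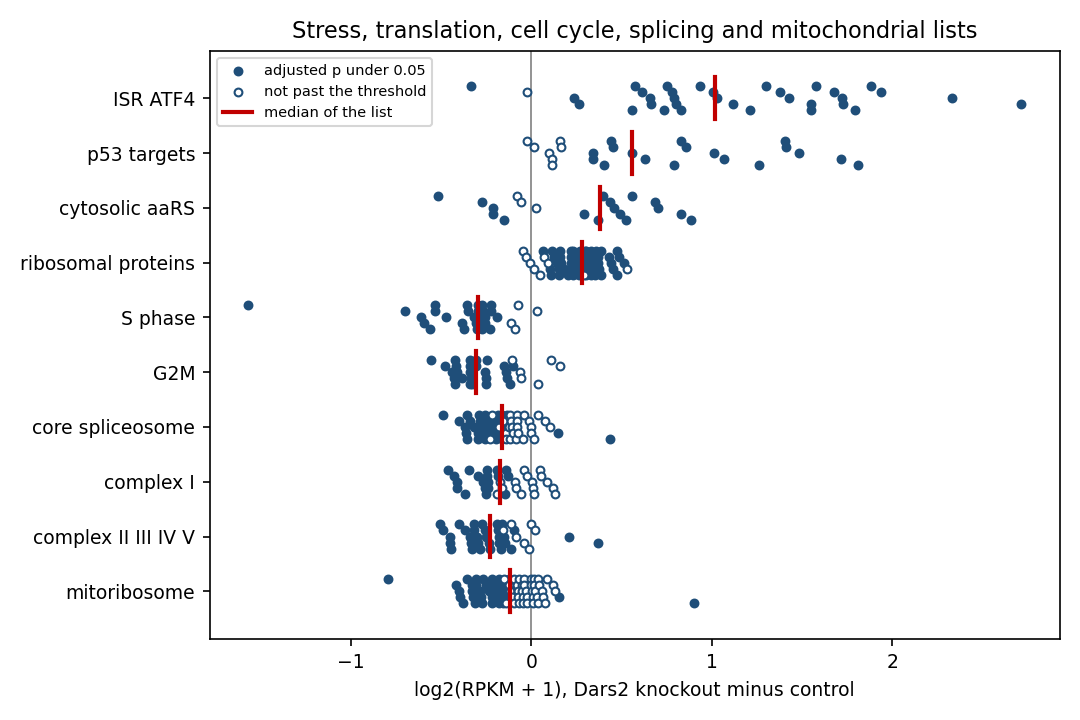
Difference in log2(RPKM + 1) between knockout and control libraries (x axis, knockout minus control) for each measured member of 10 gene lists (y axis), with filled points past an adjusted p of 0.05, open points not past it and red bars at the list medians. The medians run from -0.31 for G2 and mitosis genes to 1.02 for targets of the integrated stress response.

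The other mitochondrial aminoacyl-tRNA synthetases fell in 7 of 16 cases and rose in 1, Lars2, named after its values were seen (median -0.12, camera, adjusted p = 0.101). Iars2, the isoleucyl-tRNA synthetase, fell from 17.0 ± 0.43 to 12.6 ± 0.088 RPKM, and Hars2 had a log2 difference of -0.24. Among mitochondrial chaperones and proteases 11 of 19 fell and 3 rose (median -0.14, camera, adjusted p = 0.048, and adjusted p = 0.175 with an estimated correlation). Hspa9, the mitochondrial HSP70 chaperone, rose from 153 ± 2.5 to 248 ± 2.4 RPKM, while the proteases Afg3l2 and Htra2 had log2 differences of -0.45 and -0.38. The other members that rose were Lonp1 and Dnaja3, named after their values were seen. Without control replicate 1 or 2, or knockout replicate 1 or 3, the list did not pass (adjusted p = 0.075, 0.065, 0.063 and 0.054). Nuclear factors for mitochondrial DNA replication, transcription, RNA handling and translation fell in 8 of 30 cases and rose in 3 (median -0.03, camera, adjusted p = 0.311). The log2 differences were -0.33 for the translation elongation factor Tufm and -0.27 for the DNA polymerase Polg. The members that rose were Twnk, Mtif3 and Hsd17b10, named after their values were seen.

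The 13 protein-coding genes of the mitochondrial genome showed no shared direction: 3 rose, 4 fell and 6 did not pass (median 0.03, camera, adjusted p = 0.763). The median of this list turned to -0.10 after quantile normalization. The difference was largest in both directions in mt-Cytb (chromosome M, 14145 to 15288), which rose from 3301 ± 60.8 to 6678 ± 116 RPKM, and mt-Nd2 (chromosome M, 3914 to 4951), which fell from 813 ± 8.1 to 398 ± 7.8 RPKM. The log2 differences were 1.02 and -1.03, each with a standard error of 0.02. mt-Nd5 had a log2 difference of -0.29 and mt-Nd4 one of 0.17, and mt-Nd4 did not pass the threshold after quantile normalization (adjusted p = 0.211). The other members past the threshold were mt-Co3, mt-Nd4l and mt-Nd6, named after their values were seen. Control means were only 3.23 to 33.5 RPKM for mt-Nd3, mt-Nd4l, mt-Atp8, mt-Atp6, mt-Co3 and mt-Co2. In the other mitochondrial genes they ran from 741 to 4981 RPKM. The cause of this gap was not tested, and shared reads were checked only for mt-Nd2 and mt-Cytb. The directions of the low genes are therefore uncertain.

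**Figure D3:**
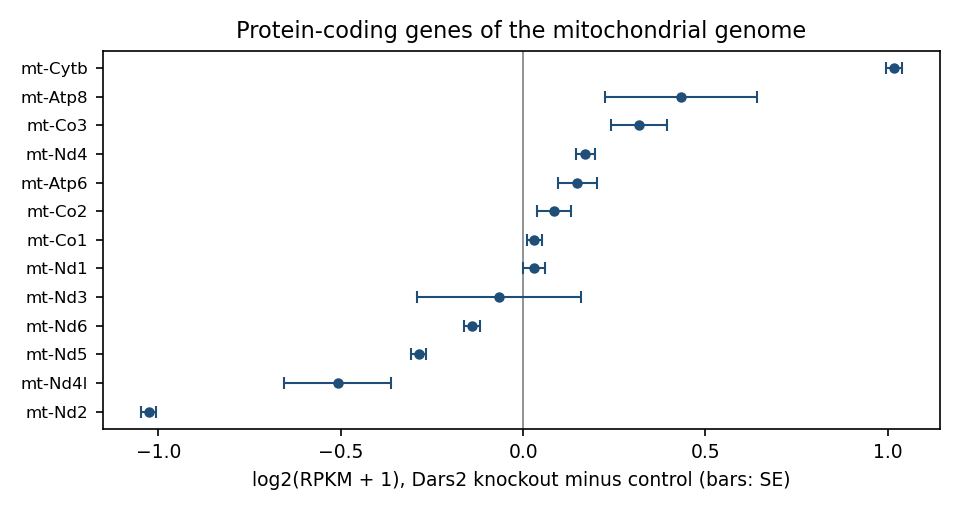
Difference in log2(RPKM + 1) between knockout and control libraries (x axis, knockout minus control, bars are the standard errors of the limma fit) for the 13 protein-coding genes of the mitochondrial genome (y axis). mt-Nd2 lies at -1.03 and mt-Cytb at 1.02. Control means of mt-Nd3, mt-Nd4l, mt-Atp8, mt-Atp6, mt-Co3 and mt-Co2 were only 3.23 to 33.5 RPKM.

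The series names messenger RNA splicing and an analysis of alternative splicing as its subject. Splicing itself was not analysed here, since the values are per gene. Among core snRNP and spliceosome proteins 32 of 60 genes fell, or 33 adjusted over the list alone, and 2 rose (median -0.16, camera, adjusted p = 2.2e-06, and 0.038 with an estimated correlation). Beside this, the erythroid median was -1.54 and the late neutrophil median 2.25. Eftud2, a GTPase of the U5 particle, fell from 27.1 ± 0.49 to 20.2 ± 0.096 RPKM, and Sf3b4 of the U2 particle from 58.7 ± 1.5 to 45.6 ± 0.55 RPKM. Sf3a2 and Ddx46 had log2 differences of -0.35 and -0.36. The members that rose were Prpf40b and Rbm22, named after their values were seen. Of 50 hnRNPs and other regulators of alternative splicing 25 fell, or 26 adjusted over the list alone, and 4 rose (median -0.12, camera, adjusted p = 0.00041, and adjusted p = 0.175 with an estimated correlation). Sfpq fell from 134 ± 1.9 to 106 ± 0.15 RPKM and Hnrnpa2b1 from 234 ± 5.9 to 187 ± 3.1 RPKM. The members that rose were Mbnl2, Taf15, Rbm39 and Rbm5, named after their values were seen. SR proteins and their kinases fell in 12 of 22 cases and rose in 4 (median -0.11, camera, adjusted p = 0.160): Srsf2 fell from 202 ± 4.4 to 162 ± 3.1 RPKM, and the kinase Srpk1 rose from 13.2 ± 0.20 to 20.8 ± 0.097 RPKM. The other members that rose were Clk1, Zrsr2 and Son, named after their values were seen. Genes of the exon junction complex and nonsense-mediated decay fell in 9 of 16 cases and rose in 2 (median -0.14, camera, adjusted p = 0.045, and adjusted p = 0.195 with an estimated correlation), with log2 differences of -0.28 for the helicase Upf1 and -0.24 for Rbm8a. The members that rose were Upf3a and Smg9, named after their values were seen. Without control replicate 1 or 2, or knockout replicate 1 or 3, this list did not pass (adjusted p = 0.064, 0.057, 0.058 and 0.053).

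Markers of the blood lineages moved apart. Erythroid genes fell in 28 of 36 cases and rose in 6, with a median log2 difference of -1.54 (camera, adjusted p = 1.5e-08, and adjusted p = 0.087 with an estimated correlation). Car1, carbonic anhydrase 1 (GRCm38 chromosome 3, 14766216 to 14808368), fell from 431 ± 3.9 to 60.8 ± 1.6 RPKM. The water channel Aqp1 fell from 152 ± 4.0 to 19.9 ± 0.23 RPKM, Ermap from 40.7 ± 0.49 to 4.40 ± 0.074 RPKM, and Rhd, a blood group antigen, from 42.5 ± 3.1 to 3.87 ± 0.39 RPKM. On the log2(RPKM + 1) scale the 10 largest falls among named genes ran from -2.67 for Sphk1, the sphingosine kinase, to -3.26 for the eosinophil ribonuclease Ear6, and included Pklr (-3.12), the pyruvate kinase of red cells and liver, Cldn13 (-3.07) and Ear1 (-2.72). By RPKM ratio the order among these 10 differs, with Rhd at 10.97-fold, Pklr at 10.8-fold and Cldn13 at 10.6-fold before Ear6 at 10.3-fold. Other genes fell by a larger ratio but are not among the 10. Examples are Add2 at 11.9-fold and Sptb at 11.06-fold, named after their values were seen. The globin genes Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2 and the erythroid heme synthesis gene Alas2, named after their values were seen, rose: Hbb-bs from 115 ± 2.4 to 420 ± 0.36 RPKM, although reads can be shared between globin copies. Genes of heme synthesis, iron uptake and iron-sulfur clusters fell in 23 of 30 cases and rose in 3, or 4 adjusted over the list alone (median -0.48, camera, adjusted p = 1.5e-06, and 0.038 with an estimated correlation). The transferrin receptor Tfrc fell from 56.2 ± 1.1 to 19.7 ± 0.42 RPKM and the heme synthesis gene Cpox from 34.7 ± 0.47 to 10.8 ± 0.16 RPKM, while Hmox1, heme oxygenase 1, rose from 10.6 ± 0.51 to 48.9 ± 0.021 RPKM. The other members that rose were Alas2 and Ftl1, named after their values were seen.

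Genes of promyelocytes and granulocyte-monocyte progenitors fell in 19 of 24 cases and rose in 3 (median -0.63, camera, adjusted p = 5.4e-08, and 0.038 with an estimated correlation). Elane, neutrophil elastase (GRCm38 chromosome 10, 79886247 to 79888215), fell from 2760 ± 15.1 to 441 ± 14.2 RPKM, Mpo, myeloperoxidase, from 3698 ± 19.0 to 1299 ± 15.3 RPKM, and Prtn3, proteinase 3, from 1702 ± 19.4 to 593 ± 5.1 RPKM. The members that rose were Chil3, Csf3r and Serpinb1a, the latter 2 named after their values were seen. Late neutrophil genes went the other way: 25 of 26 rose and 1, Hp, fell, with a median log2 difference of 2.25 (camera, adjusted p = 2.8e-16, and 0.038 with an estimated correlation). Hp was named after its values were seen. The granule protein genes Ltf and Ngp rose from 29.2 ± 0.62 to 325 ± 0.88 RPKM and from 221 ± 2.1 to 1282 ± 10 RPKM, and Retnlg (GRCm38 chromosome 16, 48872621 to 48874496) from 9.41 ± 1.2 to 486 ± 2.0 RPKM. Of the 10 largest rises among named genes on the log2(RPKM + 1) scale, the differences ran from 3.08 for the chemoattractant receptor Fpr1 to 5.55 for Retnlg and included the proteases Mmp9 (5.09) and Mmp8 (4.71), the chemokine receptor Cxcr2 (3.10), Fpr2 (3.51), Ly6g (3.28), Stfa2l1 (3.43) and Ifitm6 (3.23). By RPKM ratio Mmp9, at 61.8-fold, stood before Retnlg, at 51.7-fold. Stfa2l1 belongs to a cluster of near-identical copies. Fpr1 and Ly6g had as few as 2 and 3 reads in control replicate 3.

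**Figure D4:**
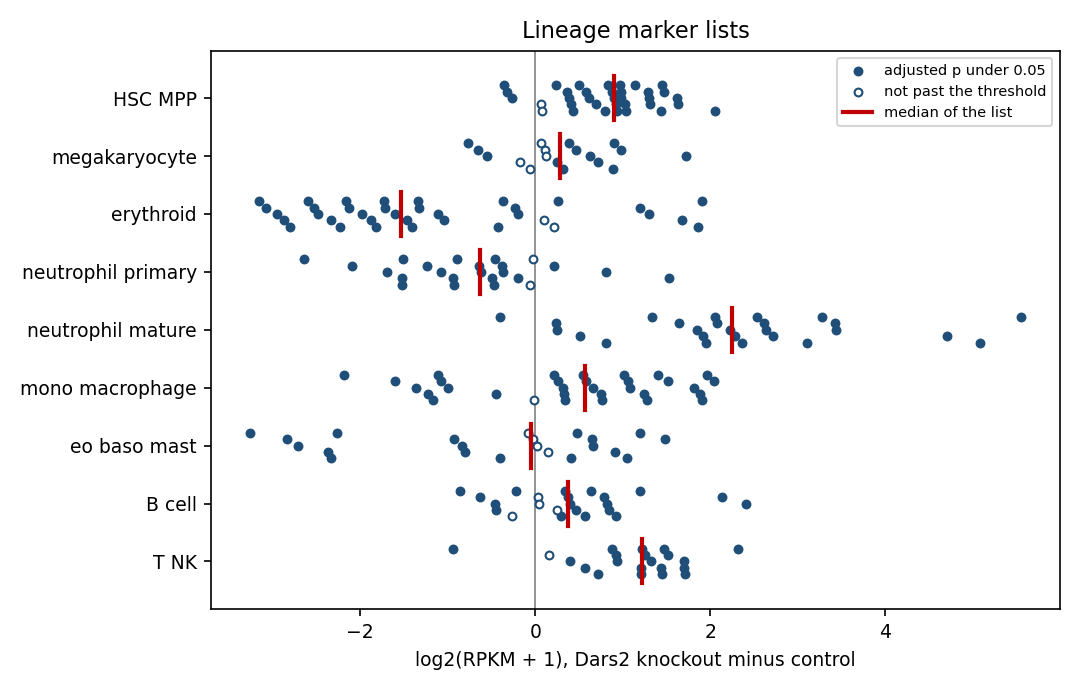
Difference in log2(RPKM + 1) between knockout and control libraries (x axis, knockout minus control) for each measured member of 9 lists of lineage genes (y axis), with filled points past an adjusted p of 0.05, open points not past it and red bars at the list medians. The erythroid median lies at -1.54, that of promyelocyte and granulocyte-monocyte progenitor genes at -0.63 and that of late neutrophil genes at 2.25.

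Genes of hematopoietic stem cells and multipotent progenitors rose in 30 of 35 cases (median 0.90, camera, adjusted p = 6.8e-10, and 0.038 with an estimated correlation). Ly6a, which encodes Sca-1, rose from 4.47 ± 0.38 to 21.7 ± 0.053 RPKM and is also a member of the list of interferon-stimulated genes, of which 31 of 41 rose. Ifitm1 rose from 42.3 ± 1.8 to 132 ± 1.2 RPKM and the receptor Flt3 from 17.8 ± 0.40 to 37.2 ± 0.32 RPKM. The 3 members that fell were Mllt3, Runx1 and Kit, named after their values were seen. Kit, the gene of the sorting marker, went from 34.2 ± 0.53 to 28.4 ± 0.66 RPKM. Mecom and Fgd5, named after their values were seen, had control means of 0.349 and 0.341 RPKM. They passed the filter only through the knockout columns. So did Prdm16, Eya1, Robo4, Rbp1 and Cdkn1c, named after their values were seen. The count and p-value of the stem cell list therefore lean toward a rise. Of 18 megakaryocyte and platelet genes 10 rose and 3 fell (median 0.28, camera, adjusted p = 0.015, and adjusted p = 0.136 with an estimated correlation). Mpl, the thrombopoietin receptor, rose from 5.04 ± 0.13 to 10.9 ± 0.49 RPKM, and the members that fell were Pf4, Vwf and Gp5, named after their values were seen.

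Eosinophil, basophil and mast cell genes went both ways, with 8 of 22 higher and 10 lower (median -0.05, camera, adjusted p = 0.161). The eosinophil granule genes fell, Epx from 237 ± 1.4 to 32.3 ± 0.92 RPKM, Prg2 from 2339 ± 47.2 to 464 ± 14.8 RPKM and Ear6 from 120 ± 2.6 to 11.7 ± 0.092 RPKM. Ear genes, however, are near-identical copies that can share reads. The 8 members that rose were Fcer1a, Cma1, Tpsb2, Gzmb, Fcer1g, Ms4a2, Cpa3 and Gata2, named after their values were seen. Fcer1a rose from 5.85 ± 0.44 to 18.2 ± 0.32 RPKM, while control means of Tpsb2 and Cma1 were only 0.168 and 0.406 RPKM. Monocyte, macrophage and dendritic cell genes rose in 22 of 32 cases and fell in 9 (median 0.57, camera, adjusted p = 0.0092, and adjusted p = 0.141 with an estimated correlation). C1qa, a complement gene of macrophages, rose from 10.8 ± 0.42 to 47.7 ± 3.6 RPKM. F13a1 fell by 2.18 on the log2(RPKM + 1) scale and the transcription factor Klf4 from 25.8 ± 0.57 to 7.85 ± 0.17 RPKM. The other members that fell were Ms4a6c, Ly86, Ccr2, Irf8, Csf1r, Cx3cr1 and Cst3, all but Ms4a6c named after their values were seen. Their log2 differences ran from -1.36 for Ms4a6c to -0.45 for Cst3. T cell, NK cell and innate lymphoid genes rose in 19 of 21 cases (median 1.22, camera, adjusted p = 5.4e-08, and 0.038 with an estimated correlation), among them Lck, from 2.32 ± 0.18 to 8.53 ± 0.23 RPKM, and Trbc2, from 0.777 ± 0.14 to 7.88 ± 0.60 RPKM. Nkg7, which granulocyte progenitors also express, was the 1 member that fell. Cd3d and Trac, named after their values were seen, had control means of 0.154 and 0.205 RPKM. Like Trbc2, they passed the filter only through the knockout columns. So did Klrb1c, Il18r1, Gata3, Cd4, Cd2, Gzma and Cd8b1, named after their values were seen. The count and p-value of this list therefore lean toward a rise. With a filter of a mean RPKM of at least 5 the T cell list did not pass (adjusted p = 0.335), nor did the monocyte list (adjusted p = 0.131). The monocyte list also missed it with a filter on 3 distinct libraries (adjusted p = 0.076). B lineage and plasma cell genes rose in 14 of 23 cases and fell in 5, or 15 and 6 adjusted over the list alone (median 0.37, camera, adjusted p = 0.015, and adjusted p = 0.136 with an estimated correlation). This list did not pass with a mean RPKM of at least 5 (adjusted p = 0.189) or with a filter on 3 distinct libraries (adjusted p = 0.103). Jchain rose from 18.5 ± 0.42 to 36.0 ± 0.73 RPKM and Cd24a fell from 177 ± 2.7 to 128 ± 3.1 RPKM. The other members that fell were Igll1, Vpreb1, Rag1 and Ighm, named after their values were seen.

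**Figure D5:**
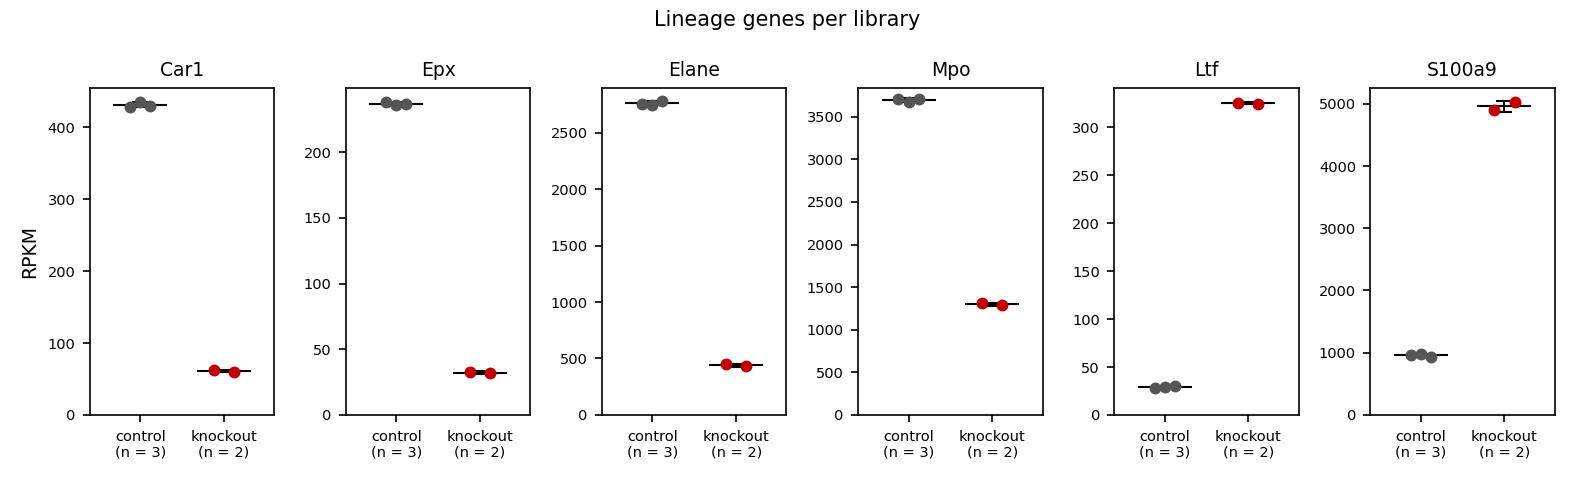
RPKM (y axis, linear, from 0) of 6 lineage genes in each library, with control libraries in grey (n = 3) and distinct knockout libraries in red (n = 2); horizontal marks are group means and bars are SD. Car1, Epx, Elane and Mpo are lower and Ltf and S100a9 higher in both knockout libraries than in all controls.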

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

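The tests of the deposited log2 values, the filter on 3 distinct libraries, limma-voom on recovered reads, the identical columns as separate libraries and the number given to them in the block were chosen after the data were seen. Dars2 was lower and past the threshold under all settings in which it was tested, with log2 differences from -1.11 to -0.79; with a mean RPKM of at least 5 it was not among the genes tested. The count of 6824 genes stayed within 1.5 times under all settings that keep the threshold, from 4757 with a mean RPKM of at least 5 to 8158 with the identical columns as separate libraries. The count of genes called higher, 3355, came to 1932 with a mean RPKM of at least 5, where fewer genes were tested. More genes were lower than higher in the main fit (3469), but more were higher with hemoglobin and mitochondrial genes left out of the scaling (3607 against 3208), with no low-expression filter (3849 against 3622) and under the replicate block (2765 against 2744, and 3019 against 3014). With an absolute log2 fold change of at least 1 the counts were 690 genes in all, 486 higher and 204 lower, by the construction of that setting; these 690 became 1162 with no added pseudocount, 1094 with log2(RPKM + 0.1), 1179 with limma-voom on recovered reads, 372 with a mean RPKM of at least 5 and 580 (376 higher, 204 lower) with a filter on 3 distinct libraries, since the main filter counts the identical knockout columns separately. Without 1 replicate at a time the count ran from 4951 to 6808, and the single knockout library was then assumed to vary like the controls. The count of gene lists called, 27, came to 10 with an estimated correlation and ran from 21 to 35 elsewhere. The replicate numbers were not taken to pair samples, since only 2 pairs exist: under the replicate block 5509 genes passed with the shared column as number 1 and 6033 as number 2, with 25 lists in each, and the correlations of deviations from the group means lay between -0.04 and 0.04.

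The direction of camera's test for the BCL2 family and caspase list (apoptosis), which camera called in no setting, turned without control replicate 2, without Dars2_KO replicate 3, after quantile normalization (median -0.0091), with a mean RPKM of at least 5 (median 0.0020) and with the identical columns as separate libraries (median 0.036). Without 1 replicate at a time its median ran from -0.00433 to 0.036. The list of mitochondrial genome genes turned after quantile normalization (median -0.0995) and in fry (median 0.030, unchanged, since fry tests another statistic); the cause of the others was not tested. Of the comparisons of named genes with their main result, 2623 were the same and 8 lost the threshold, all in Cars2, Yars2 or mt-Nd4; of those of lists, 621 were the same, 45 lost the threshold and 11 gained it. The lists of mitochondrial chaperones and of the exon junction complex missed the threshold in most settings, and in all but one of the fits that left out a library. Low values are limited by control replicate 3, with 9755603 reads.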

Other observations

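Type I interferon-stimulated genes rose in 31 of 41 measured cases and fell in 4, with a median log2 difference of 0.62 (camera, adjusted p = 3.0e-06, and adjusted p = 0.097 with an estimated correlation). Oasl2, an interferon-induced antiviral gene, rose from 1.29 ± 0.047 RPKM (SD, n = 3) to 3.76 ± 0.20 RPKM (SD, n = 2), and the RNA sensor Ddx58 from 2.36 ± 0.029 to 5.58 ± 0.23 RPKM. The list also holds Ly6a, counted among the stem cell genes. The members that fell were Isg20, Cmpk2, Gbp3 and Ly6e, of which the latter 3 were named after their values were seen. In the same libraries the late neutrophil median was 2.25, the T cell, NK cell and innate lymphoid median 1.22, the promyelocyte median -0.63 and the erythroid median -1.54. Replication-dependent histone genes, whose messenger RNAs lack poly(A) tails, rose in 14 of 17 cases and fell in 1, Hist1h1c, named after its values were seen (median 1.09, camera, adjusted p = 1.5e-05, and adjusted p = 0.087 with an estimated correlation), although histone copies can share reads. Hist1h3a went from 5.13 ± 0.35 to 16.5 ± 2.1 RPKM. This list had been fixed as a check of RNA quality, and the libraries were poly(A)-selected. The histone rise therefore cannot be read as higher histone expression alone, and the S phase list moved the other way. Immediate early genes fell in 11 of 19 cases and rose in 5, or 6 adjusted over the list alone (median -0.30, camera, adjusted p = 0.101), with lower Hspa1a, 44.5 ± 0.34 to 14.5 ± 0.47 RPKM, and higher Nr4a1, 21.4 ± 0.78 to 44.5 ± 0.35 RPKM. The other members that rose were Socs3, Junb, Zfp36 and Egr1, named after their values were seen. Of 7 endothelial, mesenchymal and osteolineage genes 4 rose and 1, Plvap, fell (median 0.30, camera, adjusted p = 0.073). Those that rose were Fabp4, Vcam1, Pdgfrb and Spp1, the last named after its values were seen.

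The metabolic lists were measured in libraries with an erythroid median of -1.54, a promyelocyte median of -0.63 and a late neutrophil median of 2.25. Among them, citric acid cycle and fatty acid oxidation genes fell in 22 of 35 cases and rose in 3 (median -0.22, camera, adjusted p = 0.00015, and adjusted p = 0.080 with an estimated correlation), such as Acaa2, from 59.3 ± 1.8 to 38.5 ± 1.3 RPKM. Those that rose were Cpt1a, Slc25a20 and Acadl, named after their values were seen. Sterol synthesis genes fell in 15 of 24 cases and rose in 2 (median -0.22, camera, adjusted p = 0.0086, and adjusted p = 0.203 with an estimated correlation), among them Dhcr7, from 7.63 ± 0.52 to 4.27 ± 0.14 RPKM. Those that rose were Hmgcs1 and Srebf2, named after their values were seen, and the list did not pass with a mean RPKM of at least 5 (adjusted p = 0.152). NRF2 antioxidant genes fell in 17 of 28 cases, or 18 adjusted over the list alone, and rose in 6 (median -0.35, camera, adjusted p = 0.0031, and adjusted p = 0.097 with an estimated correlation): Gpx1 fell from 805 ± 11 to 552 ± 4.8 RPKM and Sqstm1 rose from 51.3 ± 1.2 to 91.3 ± 1.5 RPKM. Glycolysis genes rose in 6 of 25 cases and fell in 11, with a median of -0.05, a mean of 0.002 and a test that pointed lower (camera, adjusted p = 0.258).

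The tests of a lower share of the main cell type, of total mitochondrial RNA, of a pool of cells and of the splits of the libraries were chosen only after the result was seen. Late neutrophil genes (25 of 26) and T cell, NK cell and innate lymphoid genes (19 of 21) rose in the knockout libraries. Of monocyte, macrophage and dendritic cell genes 22 of 32 rose and 9 fell (camera, adjusted p = 0.141 with an estimated correlation). These rises were seen although the sort removes cells with lineage markers. Many T cell members passed the filter only through the knockout columns. Neither the T cell nor the monocyte list passed with a mean RPKM of at least 5. A lower share of the main cell type would raise the genes of other types alike. The late neutrophil and the eosinophil, basophil and mast cell medians lay 2.30 apart (permutation test over 26 and 22 members, p = 2.0e-05). These lists therefore did not move alike, and members of the eosinophil, basophil and mast cell list went both ways. The test cannot decide on a lower share, since both medians were known beforehand and members of a list are not independent. Prg2 and Epx stood at 2339 and 237 RPKM in the controls, so these genes may not mark a type other than the main one. Lineage-positive cells carried through the sort remain open: S100a8, S100a9, Camp, Ngp and Lcn2 were all higher, by 3.61- to 6.33-fold in RPKM, but the median difference between the knockout libraries lay at percentile 82.9 of 10000 matched random lists for the late neutrophil list, 48.8 for the T cell list and 54.1 for the monocyte and macrophage list, so that the amounts did not show the variation that separate sorts could give. If both knockout libraries came from 1 sort, that test decides nothing. A change in the progenitors of the knockout, the group the design names, also stays open and was not tested.

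Within the mitochondrial genome, mt-Nd2 was lower and mt-Cytb higher in the knockout libraries. A change in total mitochondrial RNA alone would move both alike, but their log2 changes differed by 2.04 with a standard error of 0.03. That argues only against such a change as the sole cause in these genes. They were the lowest and highest of the mitochondrial genes and were picked after their values were seen. A change in the total beside their difference was not tested. Reads shared with other annotated transcripts are argued against as well: 0% of the 889 windows of 150 bases in mt-Nd2 and of the 995 in mt-Cytb occurred in a transcript of another gene. Nuclear copies outside annotated transcripts were not searched, so a technical cause outside these tests stays open beside an effect of the knockout.

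The mean chi-square per gene between libraries of 1 group was 1.73 to 2.57, where counting noise alone gives 1. Xist and Y-linked reads were both present in every library, and their ratio lay between 0.957 and 1.05 in the controls and at 0.855 and 0.784 in the knockout libraries. Within a group it differed by at most 1.10-fold, which is consistent with libraries made from 1 pool of cells of both sexes per group, as a hypothesis. Libraries from separate mixtures of equal makeup would look alike, and were not tested apart from this. If libraries came from 1 pool, the spread behind the 6824 calls would hold no variation between animals.

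Of the 10 splits of the 5 libraries, the real one was the 1 split that gave as many genes, and the highest of the others gave 0. So few splits cannot give a share under 0.05. Every other split also mixed knockout and control libraries within a group, which widens the spread there. Their counts of 0 therefore do not bear on chance.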
